A study of Mus musculus with 4 samples.

How the data were processed

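CUT&RUN was carried out on 100000 nuclei per reaction from mouse primary cortical cultures, with 5 µM cytosine arabinoside on day 3 against dividing glia, and libraries were amplified in 14 PCR cycles, per the labels' protocols. There were 2 libraries with an antibody against SATB2 and 2 with rabbit IgG, grouped by the antibody label. Trim Galore, Bowtie2 2.4.5, deepTools, SEACR 1.4 and the genome build mm10 are named, without order or role, per the submitters' processing notes. Whether peaks were called per library or on pooled reads, how the IgG libraries were used and the caller's threshold are not given in the sources used here.

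The deposited values are genomic positions, the start and end of each peak in base pairs, in one list of 14964 peaks for the series. The list has 3 columns (chromosome, start, end) and no height, score or column per library, so no test between libraries could be made and depth is unknown. Of the starts 94.6%, and of the widths 99.99%, are multiples of 50 bp, the smallest gap between neighbouring peaks is 250 bp (median 36900 bp), and widths end sharply at 100 and 5000 bp (119 and 18 peaks). A caller or later filter that bounds widths sets both the number of peaks and the median width. Analyses used the 14952 peaks on assembled chromosomes.

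Genes came from the RefSeq annotation of GRCm38.p6, whose chromosome coordinates are those of mm10. It gives gene extents without strand, exons or sequence. Tests planned on transcription start sites were therefore made on both gene ends, with 1 kb either side, and the planned 10 kb upstream became 10 kb either side. A gene end hit may thus lie at the 5′ or the 3′ end. Only the outer limits of a gene counted as ends, so a transcript start inside it was not seen as one. Exons and introns, sequence motifs and their positions, base composition and comparisons matched on GC content were not analysed here. With no signal column, peak width replaced signal wherever signal had been planned, and 1 setting keeps the 7476 widest peaks. Whether width follows signal is unknown. That setting drops more peaks at gene ends than elsewhere (median widths 1750 and 2300 bp), so a call lost there need not rest on weak signal. The planned binomial test per chromosome, which needs sequence lengths without gaps, was not run; densities use the span from the first to the last annotated gene.

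Expected shares came from 1000 random placements of the peaks, without regard to overlap, on their own chromosome between its first and last gene, with widths kept (100 for the distance bins). The two-sided permutation p cannot fall below 0.002. A peak was at a gene end when it touched the window; shares inside and outside genes used peak midpoints. Widths were compared by a permutation test with 100000 resamples. The 28 gene lists, the test settings and the rule for named genes were fixed before the data were examined. Lists defined by symbol prefix were olfactory and vomeronasal receptors, cytosolic and mitochondrial ribosomal proteins, histones, Zfp genes, clustered protocadherins and Hox genes; the others were written by hand. Of the hand-written symbols all but Cpg2 and the ambiguous Clim1 matched a gene, some through older names. Lists were tested at gene ends by two-sided Fisher's exact tests with conditional odds ratios and exact 95% intervals, and over whole genes against 10000 random lists matched on gene length in 20 bins (smallest p 0.0002), each with Benjamini-Hochberg adjustment over 28 lists and a threshold of 0.05. A further 9 pairs of lists were compared directly, leaving out shared genes and adjusted over the pairs. These pairs were not in the fixed plan. Most set a list called above against one that was not, so a difference there is no separate support for the call. Correlations across autosomes used 20000 shuffles.

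Genes named in the text were Satb2, the genes nearest to the 10 widest peaks at and away from gene ends (ties in genome order), up to 4 members of each list with the widest peak at an end, the 10 protein-coding genes with most peaks, and Bdnf, Fos, Arc, Npas4, Bcl11b, Fezf2, Tbr1, Cux1, Cux2, Rorb, Mef2c and Auts2.

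The tests were tried on simulated data. Random positions for the 14952 peaks gave 6.63% at gene ends against 6.36% expected (permutation p = 0.259), and placing 5% of them at gene ends gave 11.2% against 6.31%. Over 21887 genes, with 10 lists of 40 genes planted at 60% and 20 lists left at 33%, Fisher's test called 9 of the 10 and 1 of the 20. Where peaks depended on gene length alone, Fisher's test called 17 of 20 unchanged lists of long genes, and length-matched lists called 0 of the 20 and 6 of 10 lists planted at 90%. There the share rose evenly over all lengths and more steeply than in the data, where most of the difference lay between the shortest genes and the rest. The 17 of 20 is therefore not the rate of false calls to expect here. Alternatives were other windows and flanks, the widest peaks, merged peaks, all annotated genes, another background and, added after seeing the data, local placement within 1 Mb, lists matched on gene length or gene density, autosomes alone and genes without close neighbours. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.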

Results

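SATB2, a chromatin-binding protein and a marker of callosal projection neurons of the cerebral cortex, was mapped by CUT&RUN in primary cortical cultures of newborn mice that carried floxed Satb2 alleles. In CUT&RUN an antibody directs a nuclease to the bound protein and the DNA cut free around it is sequenced. The cultures were 14 days old; they had been silenced for 16 h with 20 µM NBQX, a blocker of AMPA-type glutamate receptors, and were then stimulated for 1 h with 50 µM bicuculline, a GABA-A receptor antagonist. There were 2 libraries with an antibody against SATB2 and 2 with rabbit IgG. The stated purpose was to find SATB2 binding sites across the genome. The list analysed holds 14964 peak positions on the mouse genome (GRCm38, also called mm10) for the series as a whole. It gives no height or library for a peak, so sequencing depth is unknown, the 2 SATB2 libraries could not be compared and no IgG value could be set beside a peak. On the assembled chromosomes lay 14952 peaks, which covered 32.4 Mb, with a median width of 2100 bp (quartiles 1500 and 2700 bp). No peak was narrower than 100 bp or wider than 5000 bp.

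At the gene for SATB2 itself (Satb2, chromosome 1, 56793981 to 56981190) no peak touched the 1 kb around either end. Peaks at 56971951 to 56973950 and 56976101 to 56978600 lay inside the gene, centred 8.24 and 3.84 kb from its higher-coordinate end, and one at 56983401 to 56985350 lay just outside that end. Among genes that define cortical layers, Cux1 and Cux2, transcription factors of upper-layer neurons, and Rorb, a nuclear receptor of the same layers, each had a peak at the higher-coordinate end. Cux2 (chromosome 5, 121857962 to 122050415) had 6 peaks within the gene and 10 kb to either side, and the one at its end, 122047301 to 122051200, was 3900 bp wide. Cux1 had 2 such peaks and Rorb 1. Of the genes for subcerebral and corticothalamic neurons, Fezf2 had a peak of 2950 bp at its end. Bcl11b, which encodes the transcription factor CTIP2, had 3 peaks inside the gene and 1 centred 2.33 kb beyond it, with none at an end, and Tbr1 had no peak within 10 kb (the nearest was 90.7 kb away).

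The activity-regulated genes differed from one another. Bdnf, which encodes a neurotrophin induced by activity, had a peak at its lower-coordinate end (chromosome 2, 109673301 to 109675500) and a second inside the gene at 109692951 to 109695300. Npas4 had a single peak of 3850 bp within its annotated extent, Arc had 2 peaks outside the gene (the nearer 3.28 kb away), and the nearest peak to Fos was 98.6 kb away. Whether the peak in Npas4 lies at a transcript start could not be told. Mef2c, an activity-regulated transcription factor gene, had 1 peak inside the gene, and Auts2, a neurodevelopmental gene of 1106 kb, had 5, against a mean of 1.68 over 100 genes of similar length. The map of peaks at 6 of these genes gives their positions.

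**Figure D1:**
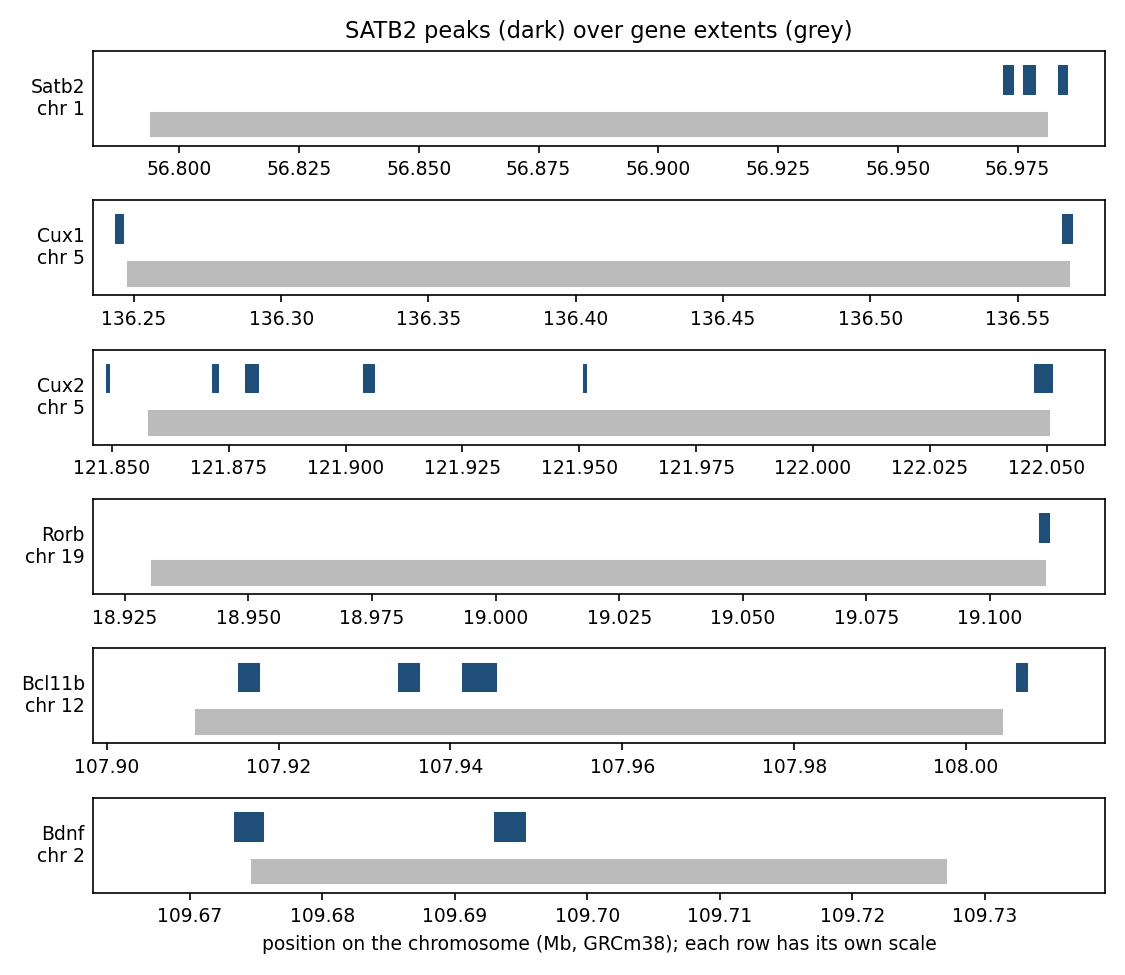
Positions of SATB2 peaks (dark blocks) over the annotated extents (grey bars) of Satb2, Cux1, Cux2, Rorb, Bcl11b and Bdnf, with 12 kb to either side; the x axis gives the position in Mb on GRCm38, and each row has its own scale. Cux1, Cux2, Rorb and Bdnf have a peak at an end, and at Satb2 the 3 peaks lie near the higher-coordinate end without covering it.

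SATB2 peaks gathered at the ends of genes. Of the 14952 peaks, 6774 (45.3%) touched the 1 kb on either side of an end of a protein-coding gene, against 6.36% ± 0.202 (SD over 1000 placements) when the peaks were placed at random on their chromosomes, a 7.12-fold excess. The p of this two-sided permutation test was 0.002, the smallest that the placements can give. When each peak was moved by up to 1 Mb only, a placement chosen after seeing the data, 11.7% ± 0.259 was expected and the excess was 3.88-fold (permutation p = 0.002). The widest peaks at gene ends, of 5000 or 4950 bp, were nearest to Tmem61, Padi2, Mknk2, Hr, Sox8, Abcf1, Disp2, Rhoc, Szt2 and Sh2b3. Sox8 is a transcription factor gene of the SoxE group, Hr encodes the nuclear receptor corepressor hairless, and Rhoc encodes a Rho GTPase. The annotation used here gives no strand, so the start and the end of a transcript were not told apart. Transcript starts inside a gene did not count as ends.

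By distance, 38.2% of the peaks covered a gene end, against 3.49% expected, and a further 7.10% lay within 1 kb of one. Beyond 100 kb lay 4.60% of the peaks, against 35.1% expected. Peaks centred outside genes made up 19.5%, below the 57.5% ± 0.397 of random placement (permutation p = 0.002, the smallest possible). Peaks centred inside genes and away from their ends made up 44.4%, above the 39.3% ± 0.384 expected (permutation p = 0.002, the smallest possible), but this excess depended on the comparison. When each peak was moved by up to 1 Mb only, 49.9% ± 0.386 was expected and the observed share lay below it; with all annotated genes in place of protein-coding ones the share was 45.2% against 45.3% ± 0.393 (permutation p = 0.755). Counting all peaks centred within 5 kb of an end as end peaks also put the remainder inside genes, 28.4%, below the 33.7% ± 0.369 expected. Among the 7476 widest peaks the share inside genes was 60%, against 39.5% ± 0.548 (1.52 times, permutation p = 0.002).

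**Figure D2:**
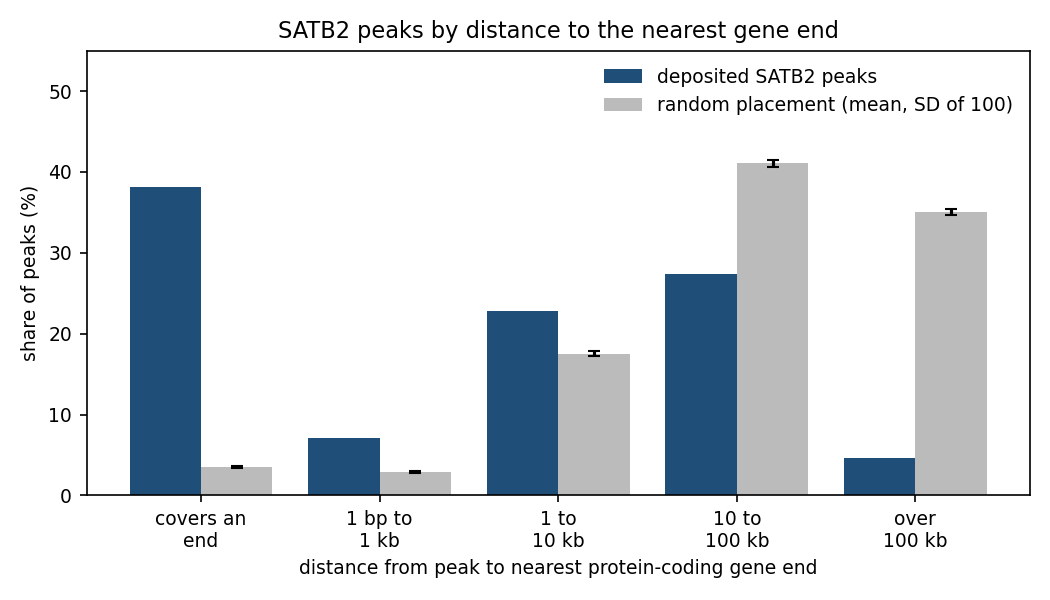
Share of the SATB2 peaks (y axis, percent) by distance to the nearest end of a protein-coding gene (x axis), for the peaks as deposited (dark) and for random placement on the same chromosome (grey, mean of 100 placements, error bars SD). Peaks that cover an end make up 38.2% against 3.49% expected, and peaks over 100 kb away 4.60% against 35.1%.

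Peaks away from gene ends were wider. Their median width was 2300 bp (quartiles 1800 and 2850 bp, 8178 peaks), and that of peaks at gene ends 1750 bp (quartiles 1300 and 2450 bp, 6774 peaks), a difference of -550 bp for end peaks minus the others (two-sided permutation test with 100000 resamples, p = 1e-05, the smallest it can give). The widest peaks away from ends, all of 5000 bp, were nearest to the ends of Glis1, Man1c1, Icmt, Ski, Relt, Nlrc5, Sipa1l2, Cacna2d2, Bahcc1 and Akt1. Ski is one of the genes of corepressor subunits in the fixed lists, and the peak nearest to it (chromosome 4, 155147601 to 155152600) lay 1.48 kb from its lower-coordinate end. Those nearest to Glis1, Man1c1, Relt, Nlrc5, Cacna2d2, Bahcc1 and Akt1 were centred inside these genes. Cacna2d2, which encodes a calcium channel subunit, held its peak 13.6 kb from its higher-coordinate end (chromosome 9, 107510701 to 107515700). Among the 7476 widest peaks, 32.9% were at a gene end, still above the 7.44% ± 0.304 expected. Width stands in here for signal, which the list does not give, and the upper bound of 5000 bp is shared by 18 peaks.

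Of 21887 protein-coding genes, 7272 (33.2%) had a peak at an end, 6314 of them at one end and 958 at both. Genes over 5 kb long had a peak at both ends less often than chance would give: 551 of 16853, against a mean of 694 (636 to 755 over 1000 shuffles of the calls at one end; permutation p = 0.002, the smallest possible). The gene lists fixed for these cultures were compared with all other protein-coding genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 28 lists. In that comparison 9 lists lay above and 3 below.

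Genes of electrical signalling and of the excitatory synapse carried peaks at their ends more often than other genes. Of 56 voltage-gated ion channel genes 34 (60.7%) had one, an odds ratio of 3.12 (95% interval 1.77 to 5.60, adjusted exact p = 0.000367). The widest were at Hcn2 (4750 bp; chromosome 10, 79716301 to 79721050), Kcnq2 (4700 bp), Cacna1h (4150 bp) and Hcn4 (4000 bp); Hcn2 and Hcn4 encode hyperpolarization-activated channels, Kcnq2 a potassium channel of the M-current and Cacna1h a T-type calcium channel. Of 46 genes of glutamate receptors and postsynaptic scaffolds 27 (58.7%) had a peak at an end (odds ratio 2.86, 1.53 to 5.45, adjusted exact p = 0.00247). They included Grin2a, an NMDA receptor subunit gene, with 4750 bp (chromosome 16, 9991351 to 9996100), Camk2b with 4700 bp, Grid1 with 3950 bp and Dlgap3, a scaffold gene, with 3800 bp. Synaptic vesicle and release genes reached 52.9% (27 of 51, odds ratio 2.27, 1.26 to 4.10, adjusted exact p = 0.0148), among them Cplx1, Bin1, Syngr1 and Syt2 with peaks of 4650, 4500, 3800 and 2800 bp.

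Axon guidance genes had a peak at an end in 29 of 55 cases (52.7%, odds ratio 2.25, 1.28 to 3.97, adjusted exact p = 0.0147), led by Efna5, an ephrin ligand gene, with 4000 bp, Nrp1, a semaphorin receptor gene, with 3500 bp, Unc5a with 3350 bp and Sema7a with 3250 bp. GABAergic interneuron genes had one in 17 of 30 cases (56.7%, odds ratio 2.63, 1.20 to 5.90, adjusted exact p = 0.0263): Nxph1, Mafb, Slc32a1 (the vesicular GABA transporter) and Gad2 (a GABA-synthesizing enzyme) had peaks of 4250, 3650, 2900 and 2850 bp. Neural progenitor genes followed with 12 of 20 (60%, odds ratio 3.02, 1.13 to 8.52, adjusted exact p = 0.0373), with peaks at Emx1 and Insm1 (3900 bp each), Nes (3200 bp) and Sox2 (3000 bp). Of the clustered protocadherins, adhesion proteins with many isoforms from one locus, 29 of 57 had a peak at an end (50.9%, odds ratio 2.09, 1.20 to 3.64, adjusted exact p = 0.0193), the widest at Pcdhgc3, Pcdhac1, Pcdhgc5 and Pcdhac2. These genes overlap, and the 29 rested on 13 distinct peaks.

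Short genes had peaks at their ends less often. With the genes in 5 equal groups by length, 17.8% of the shortest (median length 1.54 kb; 24.4% without olfactory and vomeronasal receptor genes), 34.7%, 36.0%, 36.7% and 41.0% of the longest (109 kb) had one, so most of the difference lay between the shortest group and the rest. The median lengths of the ion channel, glutamate receptor and axon guidance lists were 138, 140 and 154 kb. The lists were also compared with 10000 random lists, without matching and matched on gene length, both chosen after seeing the data. With matching the ratio to the expected share fell for voltage-gated ion channels from 1.82 to 1.50, and they stayed above (adjusted permutation p = 0.0224). The call was lost for glutamate receptors (from 1.77 to 1.43 times, adjusted permutation p = 0.0683), vesicle genes (1.60 to 1.35, 0.140), axon guidance (1.59 to 1.29, 0.194), interneuron genes (1.71 to 1.57, 0.0850) and protocadherins (1.53 to 1.37, 0.0985). Progenitor genes, with a median length of 5.79 kb, had the same ratio without and with matching (1.81 and 1.82) and missed the threshold in both (adjusted permutation p = 0.0569 and 0.0683), so their lost call does not come from length. Without olfactory and vomeronasal receptor genes in the background, the odds ratio was 2.37 for interneuron (adjusted exact p = 0.0513) and 2.72 for progenitor genes (0.0740). With 5 kb windows vesicle and progenitor genes also missed the threshold (odds ratios 1.82 and 2.57, adjusted exact p = 0.0849 for each). So did, with odds ratios close to those of the main test, vesicle genes among the 7476 widest peaks (2.13, adjusted p 0.0880) and progenitor genes on autosomes alone (2.82, 0.0672). The protocadherin call was also lost with 500 bp windows (odds ratio 1.72, adjusted p 0.106), among the widest peaks (1.13, 0.856) and against lists matched on gene ends within 100 kb (1.39 times, 0.0823). The list turned below without genes that end within 2 kb of another (odds ratio 0.430, adjusted exact p = 0.618), where 14 genes remained, 2 of them with a peak.

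Subunit genes of the BAF complex, a nucleosome remodeller, had the highest share of any list, 19 of 28 (67.9%, odds ratio 4.25, 1.83 to 10.7, adjusted exact p = 0.00139). Arid2 (4200 bp; chromosome 15, 96284751 to 96288950), Dpf3 (3450 bp), Bcl7a (3300 bp) and Arid1b (3150 bp) had the widest. The call held against length-matched lists (1.76 times, adjusted permutation p = 0.0235) and was lost among the 7476 widest peaks (odds ratio 2.30, adjusted exact p = 0.182). Without genes that end within 2 kb of another it was also lost (odds ratio 2.58, adjusted exact p = 0.178), with 14 BAF genes left, 7 of them with a peak. Genes of the NuRD and SKI corepressors (6 of 19, 31.6%; Hdac1, Chd4, Mta2 and Rbbp7 had the widest peaks) and of cohesin, CTCF and other architectural proteins (10 of 32, 31.3%; Maz, Hnrnpu, Smchd1 and Adnp) did not differ detectably from other genes (adjusted exact p = 1 for both). In direct comparison BAF genes lay above both, with odds ratios of 4.41 (1.12 to 19.5) and 4.52 (1.38 to 16.0) and an adjusted p of 0.0405 for each over the 9 pairs of lists compared. The pairs were not planned and the BAF list was already called above other genes, so this adds no separate support.

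Upper-layer and callosal genes had a peak at an end in 10 of 29 cases (34.5%; Cux2, Cux1, Plxnd1 and Bhlhe22 had the widest), and deep-layer and subcerebral genes in 11 of 29 (37.9%; Foxp1, Fezf2, Dkk2 and Lratd2). Neither list differed detectably from other genes (adjusted exact p = 0.987 and 0.755), nor did they from each other (odds ratio 0.863, 0.257 to 2.87, adjusted p = 1). Counting the 7476 widest peaks alone, 9 of the 29 deep-layer genes had one and the list lay above other genes (odds ratio 3.11, adjusted exact p = 0.0302). Immediate early genes, the first genes transcribed after stimulation, had a peak at an end in 12 of 32 cases (37.5%, odds ratio 1.21, 0.537 to 2.59, adjusted exact p = 0.755), with 4100 bp at Klf4, 3700 bp at Fosb, 3500 bp at Egr3 and 3200 bp at Junb. Late activity-response genes had one in 8 of 29 cases (27.6%, adjusted exact p = 0.844; Gpr3, Sorcs3, Tiparp and Bdnf). The 2 activity lists did not differ detectably (odds ratio 1.56, 0.470 to 5.43, adjusted exact p = 0.484).

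Synaptic adhesion genes (23 of 63, 36.5%; Lrrc4, Adgrl3, Ptprs and Clstn1), GABA receptor genes (6 of 15, 40%; Gabbr2, Gabbr1, and Gabra5 and Gabrb3, which share a peak) and autism and intellectual disability genes (20 of 60, 33.3%; Tsc2, Nsd1, Foxp1 and Arid1b) did not differ detectably from other genes (adjusted p of 0.755, 0.755 and 1). Ion channel and glutamate receptor genes lay above the adhesion genes in direct tests (odds ratios 2.66 and 2.45, adjusted exact p = 0.0405 and 0.0479). Both higher lists were already called above other genes, so these unplanned tests add no separate support. Glutamate and GABA receptor genes did not differ detectably (odds ratio 2.10, 0.559 to 8.51, adjusted exact p = 0.313).

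Lists of glia, vessel cells and liver did not lie above other genes. Astrocyte genes had a peak at an end in 4 of 20 cases (Ndrg2, Aldoc, Aldh1l1 and Slc1a2), oligodendrocyte lineage genes in 5 of 20 (Sox10, Mbp, Olig1 and Olig2 had the widest), endothelial and mural cell genes in 6 of 20 (Egfl7, Cldn5, Pdgfrb and Erg) and liver genes in 8 of 30 (Apoa1, Cyp8b1, Apob and Ambp), with adjusted p of 0.427, 0.755, 1 and 0.755. Microglia genes had the lowest share of these, 2 of 20 (Spi1 and Sall1; odds ratio 0.223, 0.0251 to 0.932, adjusted exact p = 0.0658), which passed the threshold when olfactory and vomeronasal receptor genes were left out (adjusted p = 0.0494). Interneuron and progenitor genes lay above astrocyte genes in direct tests (odds ratios 5.05 and 5.71, adjusted exact p = 0.0405 for each). Both higher lists were already called above other genes, so these unplanned tests add no separate support.

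Among gene families not particular to neurons, mitochondrial ribosomal protein genes lay above the background (38 of 78, 48.7%, odds ratio 1.91, 1.19 to 3.06, adjusted exact p = 0.0164), with wide peaks at Mrpl54, Mrpl38, Mrpl43 and Mrpl12. Cytosolic ribosomal protein genes reached 43.4% (33 of 76, odds ratio 1.54, 0.950 to 2.49, adjusted exact p = 0.125; Rps15, Rpl12, Rps6 and Rps17) and passed only against length-matched lists (1.50 times, adjusted permutation p = 0.0408) and without genes that end within 2 kb of another (odds ratio 2.32, 0.0405). Genes with the Zfp prefix, most of them zinc finger transcription factors, reached 37.8% (150 of 397, odds ratio 1.23, 0.991 to 1.51, adjusted exact p = 0.106; Zfp469, Zfp335, Zfp36l2 and Zfp651). Leaving out genes that end near another put the Zfp list above (odds ratio 1.58, adjusted exact p = 0.00121). Among the 7476 widest peaks the Zfp list turned below other genes (odds ratio 0.560, adjusted exact p = 0.00621) and the mitochondrial ribosomal list no longer differed detectably (0.900, adjusted p = 1).

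Receptor genes of the nose were almost free of peaks. Of 1465 olfactory and vomeronasal receptor genes 10 had a peak at an end (0.683%, odds ratio 0.0125, 0.00596 to 0.0230, adjusted exact p = 7.50e-245), with the widest at Olfr1415, Olfr522, Olfr374 and Olfr156. Hox genes, which pattern the body axis, had one in 2 of 39 cases (odds ratio 0.108, 0.0127 to 0.420, adjusted exact p = 0.000456): Hoxa5 and Hoxa6 shared the peak at 52202501 to 52204800 on chromosome 6. Among the 7476 widest peaks the Hox difference missed the threshold (odds ratio 0.373, adjusted exact p = 0.394). Replication-dependent histone genes had a peak at an end in 8 of 57 cases (14.0%, odds ratio 0.327, 0.134 to 0.698, adjusted exact p = 0.00784), on 6 distinct peaks; H2ac24, H4c11, H4c18 and H3c11 had the widest, of 950 to 1000 bp. The histone genes are short (median 0.487 kb), and against length-matched lists they lay above the expected share (2.64 times, adjusted permutation p = 0.0408). The call was lost with 5 kb windows (odds ratio 0.637, adjusted exact p = 0.243). Without genes that end near another the odds ratio was 2.07 (adjusted exact p = 0.504) over the 9 genes left, 4 of them with a peak. Histone and receptor genes have near-identical copies, where reads that map to several copies can change which peaks are called. Receptor, Hox and histone genes also lie in clusters, where neighbours can share a peak or its absence. Fisher's test counts each gene separately, so for these lists its p and intervals understate the spread.

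**Figure D3:**
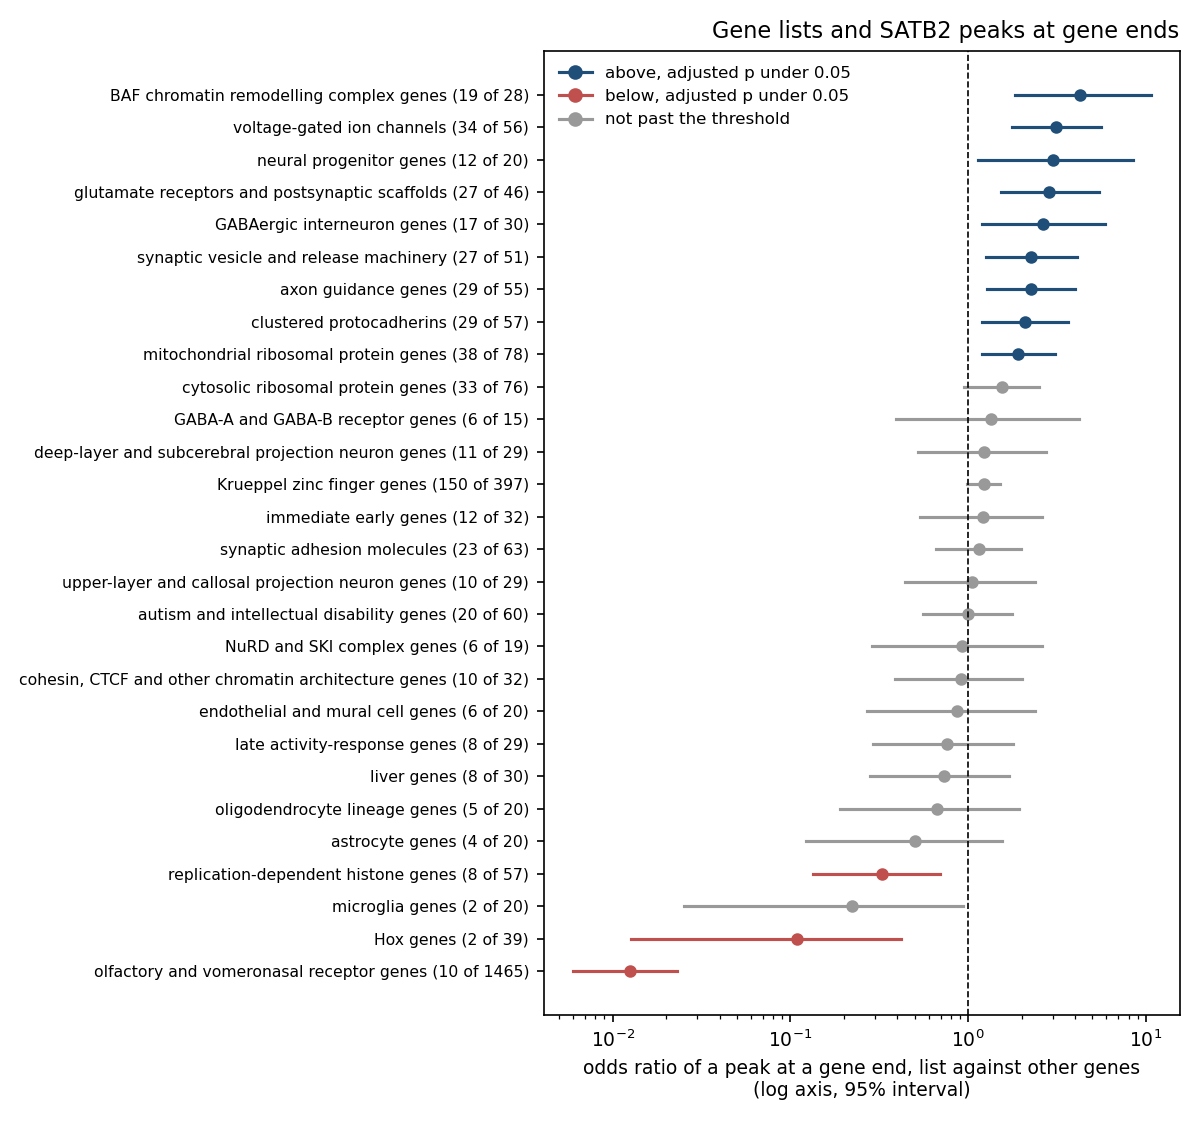
Odds ratio of a SATB2 peak at a gene end for each of the 28 gene lists against all other protein-coding genes (x axis, log scale; points are estimates and lines 95% intervals), ordered by the share of genes with a peak, whose counts stand beside the names. BAF complex genes (19 of 28) stand at the top and olfactory and vomeronasal receptor genes (10 of 1465) at the bottom.

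Several of these lists also stood apart when whole genes with 10 kb to either side were counted and gene length was matched. A peak was found for 10944 (50.0%) of the protein-coding genes. Against 10000 length-matched random lists (two-sided permutation p, Benjamini-Hochberg adjusted over 28 lists), glutamate receptor and scaffold genes had a peak in 82.6% of cases against 61.7% ± 7.06 expected (adjusted p = 0.0112), ion channels in 82.1% against 60.7% ± 6.48 (0.00560), BAF genes in 85.7% against 57.8% ± 9.28 (0.0147) and protocadherins in 77.2% against 55.1% ± 6.41 (0.00560). Cytosolic and mitochondrial ribosomal protein genes (64.5% against 42.1% ± 5.58, and 62.8% against 48.8% ± 5.58; adjusted permutation p = 0.00140 and 0.0420) and histone genes (36.8% against 11.4% ± 3.81, 0.00140) also lay above. Histone and protocadherin genes lie close together or overlap (9 and 14 of the 57 genes in each list end more than 2 kb from another gene). A single peak can thus count for several members, while random lists draw genes without regard to position. For these lists the SD and p understate the spread. With 50 kb to either side the glutamate receptor and BAF calls were lost (1.17 and 1.27 times, adjusted permutation p = 0.160 and 0.0516), and NuRD and SKI genes passed above (19 of 19, 1.38 times, 0.0196) and liver genes below (0.663 times, 0.0376). Counting the gene alone, the mitochondrial ribosomal call was lost at a ratio no lower than in the main test (1.33 against 1.29, 0.0977), the histone call was lost (2.02 times, 0.187) and progenitor genes passed (1.85 times, 0.0378). By Fisher's exact test, without length matching, the mitochondrial ribosomal call was lost (odds ratio 1.69, adjusted p = 0.0657), the histone list lay below other genes (odds ratio 0.582, 0.0953), and upper-layer (odds ratio 3.15, 0.0226), vesicle (2.19, 0.0277), axon guidance (3.24, 0.000520) and autism and intellectual disability genes (2.34, 0.00922) passed. Random lists without matching, which keep the form of the test and were added after seeing the data, gave the same calls; the mitochondrial ribosomal ratio was 1.25, against 1.29 with matching (adjusted permutation p = 0.0702). Among the widest peaks both ribosomal lists lay below the expected share without passing the threshold (0.784 and 0.857 times, adjusted permutation p = 0.470 and 0.648), and Zfp genes passed below (0.550 times, 0.00140).

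Below the length-matched lists lay olfactory and vomeronasal receptor genes (1.84% against 19.5% ± 0.777, adjusted permutation p = 0.00140), Hox genes (15.4% against 46.9% ± 7.86, 0.00140) and microglia genes (4 of 20, against 52.1% ± 11.2, 0.0174). Receptor and Hox genes lie in clusters as well, so for them the SD and p also understate the spread. The Hox and microglia calls were lost with 50 kb to either side (0.766 and 0.844 times, adjusted permutation p = 0.134 and 0.552) and among the widest peaks (0.577 and 0.535 times, 0.261 and 0.456). With the gene alone the microglia list missed the threshold at about the same ratio (0.372 against 0.384, adjusted permutation p = 0.0711). Immediate early genes had a peak in 20 of 32 cases (62.5% against 47.4% ± 8.59, adjusted permutation p = 0.236). Among the 7476 widest peaks they lay above (18 of 32, 2.13 times the expected share, adjusted permutation p = 0.00448), as did axon guidance genes (30 of 55, 1.68 times, 0.00560). Upper-layer genes had a peak in 22 of 29 cases (75.9% against 57.1% ± 8.90, adjusted permutation p = 0.123), and deep-layer genes in 19 of 29 (65.5% against 59.3% ± 8.86, 0.724).

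SATB2 peaks lay close together, and some genes held many. Gse1, a gene of 353 kb on chromosome 8 (120228501 to 120581383), had 29 peaks within the gene and 10 kb to either side, against a mean of 1.43 over 100 genes of similar length. Next came Zfp469 with 21, Prdm16, a transcription factor gene, with 19, Rbfox3, which encodes the neuronal marker NeuN, with 18, the cadherin gene Cdh23 with 17, Camta1 with 16 and Cdh4 with 15. The remaining 3 of the 10 genes with most peaks, Gm37013 (21), Gm38666 (19) and Gm38667 (18), are overlapping gene models that span the protocadherin cluster on chromosome 18. Over all peaks, 36.2% lay within 10 kb of another, against 14.9% ± 0.391 in random placement and 30.1% ± 0.423 when each peak was moved by up to 1 Mb (p = 0.002 in both permutation tests, the smallest possible). Merging peaks under 5 kb apart left 17 regions at Gse1.

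The X chromosome held few peaks. It carried 100, or 0.669% of the 14952 (exact 95% interval 0.544% to 0.813%, for counting error only), and 0.586 per Mb against 6.08 per Mb on autosomes, where the range was 3.08 (chromosome 3) to 10.5 (chromosome 11). Of 966 X-linked protein-coding genes 87 (9.01%) had a peak at an end, against 7185 of 20665 autosomal genes (34.8%; 27.7% to 41.6% by chromosome; odds ratio 0.186, 0.147 to 0.232, Fisher's exact p = 4.73e-75). The Y chromosome had 4 peaks, and 0 of its 256 genes had one at an end. Across the 19 autosomes the number of peaks followed the number of protein-coding genes (Pearson's r = 0.85, Spearman's rho = 0.90, permutation p = 5e-05 for both, the smallest possible), and r was 0.87 without chromosomes 7 and 2, those farthest from the median. Among the 7476 widest peaks the X share was 0.107%. Genes and peaks are not biological replicates, so these p-values describe this peak list and not the spread between cultures.

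**Figure D4:**
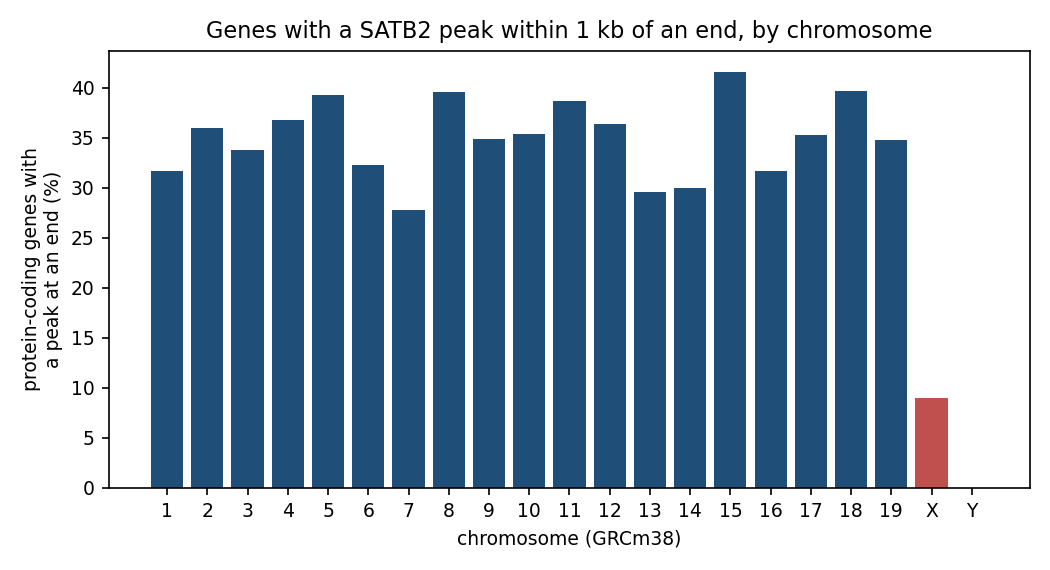
Share of protein-coding genes with a SATB2 peak within 1 kb of an end (y axis, percent) on each chromosome of GRCm38 (x axis; autosomes dark blue, X and Y red). Autosomes range from 27.7% to 41.6%, X stands at 9.01% and Y at 0.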

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

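Outside the assembled chromosomes, which the comparisons used, the list holds 12 peaks on 6 sequences. They stand out because they lie in data that no comparison used, and no IgG value was available to set beside them. Of these, 10 lie on 4 sequences assigned to chromosome 1 without a position and 2 on sequences with no chromosome. Their widths run from 650 to 3150 bp, within the range of the other peaks.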

How the results depend on the processing

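No paired analysis was possible because the peak list has no columns per library; for the same reason leaving out each replicate could not be run. Settings that need signal (maximum, per base) or sequence (GC matching, all motif settings) were not run. Of the values that answer a comparison, 63 stayed on their side of the threshold or within 1.5 times (or the counting interval), and of values of single lists or genes 331 did, 31 fell short of the threshold and 18 passed it. Lists that changed direction count as reversed below if they passed the threshold in the main or the alternative setting, and as unchanged if in neither, such as cytosolic ribosomal genes among the widest peaks (from 1.54 to 0.591) and GABA receptors without close neighbours (1.34 to 0.574). Local placement, random lists with and without matching on gene length or density, autosomes alone, genes without close neighbours, merging within 5 kb and leaving out the widest peaks were chosen after seeing the data.

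The widest 50% are 7476 peaks by construction; the X share was 0.107% among them and 0.849% after merging peaks within 10 kb. The share inside genes (44.4%) turned from above to below expectation with local placement and with 5 kb around gene ends (28.4%), which moves peaks from one class to the other, and did not differ detectably from expectation with all annotated genes (45.2% against 45.3%). Lists called at gene ends, 12 by Fisher's test (9 above), were 11 against random lists without matching (8 above) and 7 with length matching (5 above). Merging within 5 kb took Gse1 from 29 to 17. Lists that reversed at gene ends were mitochondrial ribosomal (0.900) and Zfp genes (0.560) among the widest peaks, histones with length matching (2.64), and histones (2.07, 9 genes left) and protocadherins (0.430, 14 genes left) without close neighbours. Over whole genes, cytosolic ribosomal (0.784), mitochondrial ribosomal (0.857), histone (0 of the 57 genes, ratio 0) and Zfp genes (0.550) reversed among the widest peaks, and histones without length matching (odds ratio 0.582; 0.737 times random lists). The histone calls with length matching were made against other short genes, which had few peaks. In the shortest of the 5 length groups (4378 genes, 3150 without receptor genes) 17.8% had an end peak, and 24.4% without receptor genes. Matching without receptor genes was not run, so the part played by short length alone stays open. Keeping the widest peaks leaves those of about 2100 bp or more and drops narrow ones. End peaks of mitochondrial ribosomal and Zfp genes had medians of 1175 and 1350 bp, against 1750 bp for other end peaks. Their reversals at gene ends among the widest peaks thus follow from peak width. The cause of the remaining reversals was not tested. Depth is unknown, so sites missed for lack of reads cannot be told from unbound ones.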

Other observations

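The comparisons of widths by list, the gene families by symbol and the gene types were chosen after seeing the data, as were the tests below of chromosome position and of ion channels alone. The width of end peaks differed for some lists. Of 18 lists with at least 10 distinct end peaks, voltage-gated ion channels (37 peaks, median 2350 bp against 1750 bp for other end peaks, adjusted permutation p = 0.0179) and axon guidance genes (30 peaks, 2350 bp, 0.0256) lay above. Mitochondrial ribosomal protein genes (42 peaks, 1175 bp, 0.0179) and Zfp genes (153 peaks, 1350 bp, 0.000900) lay below (two-sided permutation tests, Benjamini-Hochberg adjusted). The other lists did not pass the threshold, among them glutamate receptor (2200 bp, adjusted permutation p = 0.0595), interneuron (2250 bp, 0.105), vesicle (2050 bp, 0.193), adhesion (2100 bp, 0.153), upper-layer (2100 bp, 0.357), cytosolic ribosomal (1350 bp, 0.0780) and BAF genes (1775 bp, 0.959).

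Among 181 families of genes that share a symbol stem, several outside the fixed lists had a peak at an end more often than other genes (Fisher's exact test, adjusted over the families). Wnt ligand genes had one in 14 of 19 cases (odds ratio 5.64, adjusted exact p = 0.00330), sorting nexins (Snx) in 20 of 30 (4.03, 0.00277) and receptor tyrosine phosphatases (Ptpr) in 15 of 21 (5.03, 0.00413; 4 of these genes are also in fixed lists). Others above included Stk (16 of 22), Fbxo (21 of 36), Nduf (26 of 49), Gtf (14 of 23) and Vps genes (19 of 35). Their adjusted exact p were 0.00297, 0.0128, 0.0247, 0.0280 and 0.0397. Gene length was not matched in the family tests. Among those below were Pram genes (0 of 49), beta-defensins (Defb, 0 of 42), keratin-associated protein genes (1 of 56, Krtap10-4) and Rhox genes (0 of 33), with adjusted p of 1.48e-07, 1.46e-06, 1.59e-07 and 4.16e-05. Keratin (Krt, 13 of 53), Tex (9 of 39), Wfdc (7 of 18), Prss (14 of 39) and Spat genes (12 of 35) did not differ detectably (adjusted p of 0.366, 0.418, 0.804, 0.893 and 0.926). Cytochrome P450 genes had one in 17 of 99 cases (odds ratio 0.415, adjusted exact p = 0.00411). Of other gene types, 13.4% of long noncoding RNA genes had a peak at an end, and 5.57% of those apart from protein-coding genes; pseudogenes had one in 2.49% of cases.

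Few peaks on the X chromosome may reflect its gene content or a lower signal. If silent gene families on X were the cause, X-linked members of the hand-written lists would carry peaks as often as autosomal ones; they did so in 5 of 29 cases against 282 of 644 (odds ratio 0.268, 0.0788 to 0.728, Fisher's exact p = 0.00621), which argues against it as the whole cause. Lower signal from X, as with fewer X copies in cultures of both sexes, predicts narrower peaks, and the 76 end peaks on X had a median of 1200 bp against 1750 bp on autosomes (a difference of -550 bp, permutation p = 0.00011). Lower signal would give this. Narrow end peaks were not particular to X, though: mitochondrial ribosomal protein genes had a median of 1175 bp and Zfp genes 1350 bp. The list gives no signal against which width could be checked, so the test cannot decide. The sex of the cultures is not given, and filtering by the caller was not tested. No biological explanation was tested.

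Many peaks within single genes could be one broad domain split by the caller. With peaks under 5 kb apart merged, the 10 genes still held 12 to 19 regions, which argues against splitting over such gaps as the whole cause. The median was 14 regions, against a median 95th percentile of 5 for genes of similar length, and all 10 genes exceeded theirs. The genes were picked for their many peaks, so exceeding that percentile is no separate support. Gm37013, Gm38666 and Gm38667 overlap and are not separate cases. Position in the distal part of a chromosome stays open: taking 1 gene for each of the 6 chromosomes, 4 lay within 15 Mb of the last annotated gene, against 13.7% of length-matched genes (exact binomial p = 0.00415). Base composition, which differs along chromosomes, was not tested for want of sequence. No biological explanation was tested.

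The excess of 6 neuronal lists at gene ends (glutamate receptors, ion channels, vesicle genes, axon guidance, interneuron genes and protocadherins) could come from local gene density or gene length. Against lists matched on local gene density 5 of the 6 stayed above, which argues against density as the whole cause. With gene length matched 1 stayed above, ion channels, whose ratio to the expected share fell from 1.82 to 1.50 (adjusted permutation p = 0.0224). The rule set beforehand for the 6 lists together was met neither way, so it cannot decide. Ion channels kept an excess over length-matched lists, but they were singled out after this was seen, and the prediction for them alone adds no support. The ratios of the other 5 lay between 1.53 and 1.77 without matching and between 1.29 and 1.57 with it, and fell least for interneuron genes (1.71 to 1.57). With matching they no longer passed the threshold, which leaves length as a possible cause of part of their excess and does not exclude it as the whole. A preference for ends of genes active in every cell was not tested and stays open. Mitochondrial ribosomal protein genes also lay above other genes (48.7%). Among the widest peaks alone they did not (odds ratio 0.900), but their end peaks were narrow (median 1175 bp), so that setting drops many of them. Cytosolic ribosomal protein genes (43.4%) did not pass the threshold in Fisher's test (adjusted exact p = 0.125). Against length-matched lists, where 1 of the 6 neuronal lists stayed above, both ribosomal lists lay above. Their ratios were 1.50 (cytosolic, adjusted permutation p = 0.0408) and 1.49 (mitochondrial, adjusted permutation p = 0.0224). A comparison of the neuronal lists with ribosomal protein genes was run and dropped, because the neuronal lists had been chosen by their outcome. No biological explanation was tested.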
